A study of Gallus gallus with 9 samples.

How the data were processed

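Expression was measured in 9 samples of chicken preadipocytes, in 3 groups of 3: untreated control, an adipogenic cocktail named DMIOA, and DMIOA plus 10 uM retinoic acid. The labels number biological replicates 1 to 3 in each group and do not expand DMIOA or say which hen or culture a replicate came from, so p-values measure the spread between these samples. The control and DMIOA titles end in "(2)" and the retinoic acid titles do not, and what this marks is not given in the sources used here. A difference in handling that it might mark would be part of both retinoic acid comparisons. Retinoic acid replicates 1 and 2 were the closest pair of arrays (r = 0.997). If they were not separate cultures, the p-values of these comparisons would be too small. All 9 arrays share 1 estimate of the spread, so the p-values of DMIOA against control could then be too small as well. Per the labels' protocols, total RNA was extracted with TriZol and 15 ug of biotinylated aRNA was prepared by a 3' in vitro transcription kit for the array. The deposited values are log2 expression values per probe set made by the authors with GCRMA, per the submitters' processing notes; its version and settings are not given in the sources used here. GCRMA adjusts probe intensities for background by probe sequence, normalizes between arrays and summarises each probe set, and the log2 scale was read from the values, which run from 0.362 to 15.0. The array medians lay between 2.49 and 2.54. Scanner files and detection calls were not used here, so signal over background was judged from the log2 level alone.

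The table held 38535 probe sets: 37693 of chicken, 96 array controls, 57 reporters and 689 of other sequences. Names came from the platform annotation that goes with the table, in which 27178 probe sets had 1 gene symbol, 177 several and 11180 none. The gene IDs of 26863 of the 27178 were found in the RefSeq gene table, which changed 0 symbols. No name was taken from a probe set with several symbols, and no coordinates are given because the sources used here tie no genome build to the probe sets. Chicken probe sets with a log2 value of at least 5 on at least 3 arrays were kept, 12329 in all, of which 10243 had 1 symbol. Where a gene had several probe sets, the one with the highest mean stood for it.

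All 9 arrays were fitted with a mean per group in limma 3.58.1 (R 4.3.3; lmFit and eBayes), which gives 6 residual degrees of freedom, or 4 with the replicate number as a block. The p-values were adjusted by the Benjamini-Hochberg method over all kept probe sets and called under 0.05. Where an array of the dimmer group lay below a log2 value of 5, the fold is given as "at least", with 5 in place of each such value. The filter, the fit, 22 gene lists, their test and all alternatives but the 3 named below were fixed before the data were examined. Those with at least 3 measured members, 21, were tested with camera at a preset correlation of 0.01, with the estimated correlation and with fry, which tests whether a list's genes move one way and does not compare them with other genes. The erythroid list had 1 measured member and was not tested (its log2 differences were 0.27, -0.08 and 0.19 in the 3 comparisons). Fry called 1, 6 and 11 lists in the order of the comparisons given here. Genes were named by a rule fixed at the same time: the 10 largest rises and 10 largest falls in fitted log2 difference among called genes whose groups do not overlap, up to 4 members of each list, and a set of adipocyte, retinoid and glucocorticoid genes. Not every gene so named is described in every comparison. Lists not described in a comparison were not called there by camera with all arrays.

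The replicate numbers pair the samples by their deviations: over the 9 same-numbered pairs of samples from different groups, the deviations from the group means correlated at r = 0.375 to 0.857, each above 0.1. The pairing comes mainly from replicate 3. Between replicates 1 and 2 the crossed pairs correlated at 0.321 to 0.668 and the same-numbered ones at 0.375 to 0.730. Blocked values are given where they change a call described here or move the total count of probe sets by over 1.5 times. They are given for many, but not all, list counts and not for the 2-fold counts.

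The scripts were tested on simulated data. With 200 of 12329 probe sets changed between DMIOA and control and the real replicate effects, the fit recovered 33.4% of 2-fold and 75.0% of 4-fold changes, and 0.551% of its calls were false. With the block it recovered 55.6% and 88.2%, and 6.38% of its calls were false. For camera with 6945 uncorrelated genes, 4.76% of unchanged lists had p under 0.05. Alternatives covered the filter, centring of the arrays, cyclic loess, an intensity trend with a robust prior, array weights, the arrays entered, the replicate block, a 2-fold threshold, the list test and leaving out each array; those on replicates 1 and 2 alone, the block without DMIOA replicate 2 and the block with an estimated correlation were added after the data were seen. Figures were drawn with matplotlib 3.10.9.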

Results

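Preadipocytes, the fat-cell precursors, had been isolated from the abdominal fat of laying hens, grown to confluence and left untreated (control), given an adipogenic cocktail that the labels name DMIOA, or given the same cocktail with 10 uM retinoic acid. Retinoic acid is the vitamin A derivative that activates the retinoic acid receptors. RNA of 9 samples, 3 per group, was labelled with biotin and hybridised to a 1-colour Affymetrix chicken array with 38535 probe sets. On each array between 30.9% and 31.3% of the 37693 chicken probe sets had a log2 value of at least 5, and 12329 probe sets that reached this level on at least 3 arrays were compared. These held 6945 named genes. All levels below are log2 GCRMA values, and the number of arrays limits their precision.

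The samples parted by replicate number as well as by treatment. The first principal component, with 43.6% of the variance, set replicate 3 of the 3 groups (scores 44.7 to 67.1) apart from replicates 1 and 2 (-50.8 to -2.12), and the second, with 35.1%, set the retinoic acid arrays above those of the same replicate number. On the third, with 10.1%, DMIOA replicate 2 stood apart at 50.2, with the others between -16.2 and 16.7. Across probe sets, replicates 1 and 2 of a group correlated at r = 0.963 to 0.997 (0.997 between those with retinoic acid, 0.995 in control and 0.963 with DMIOA), and replicate 3 correlated with the replicates of its own group at 0.912 to 0.931 and with replicate 3 of the other groups at 0.940 to 0.974. Markers of macrophages and other leukocytes moved with replicate 3. The median of the 12 measured members of this list was 2.10 and 2.36 in control replicates 1 and 2 and 9.54 in control replicate 3. It was 2.21, 2.13 and 8.65 in the DMIOA arrays and 2.33, 2.34 and 7.34 in the retinoic acid arrays. The complement genes C1QB and C1QC and the macrophage receptor gene CSF1R stood at 10.93, 10.43 and 9.60 in control replicate 3, and at no more than 2.07, 2.44 and 2.50 in replicates 1 and 2 of all groups.

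**Figure D1:**
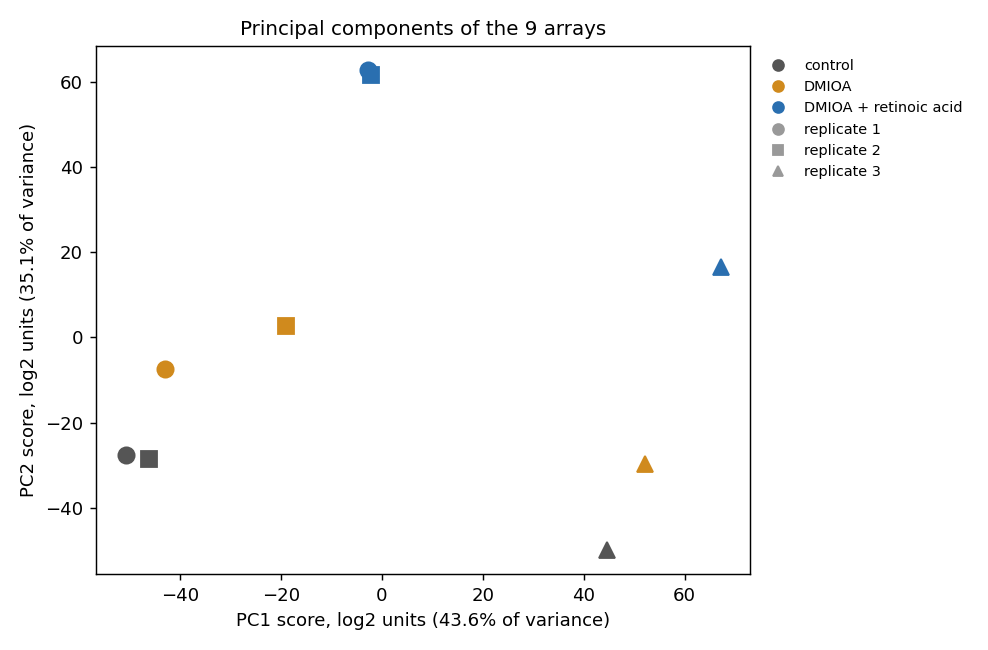
Scores of the 9 arrays on the first (43.6% of the variance) and second (35.1%) principal components of 12329 probe sets, in log2 units; colours are groups and symbols are replicate numbers. The 3 replicate 3 arrays lie at 44.7 to 67.1 on the first component, to the right of all other arrays, and the retinoic acid arrays lie highest on the second.

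**Figure D2:**
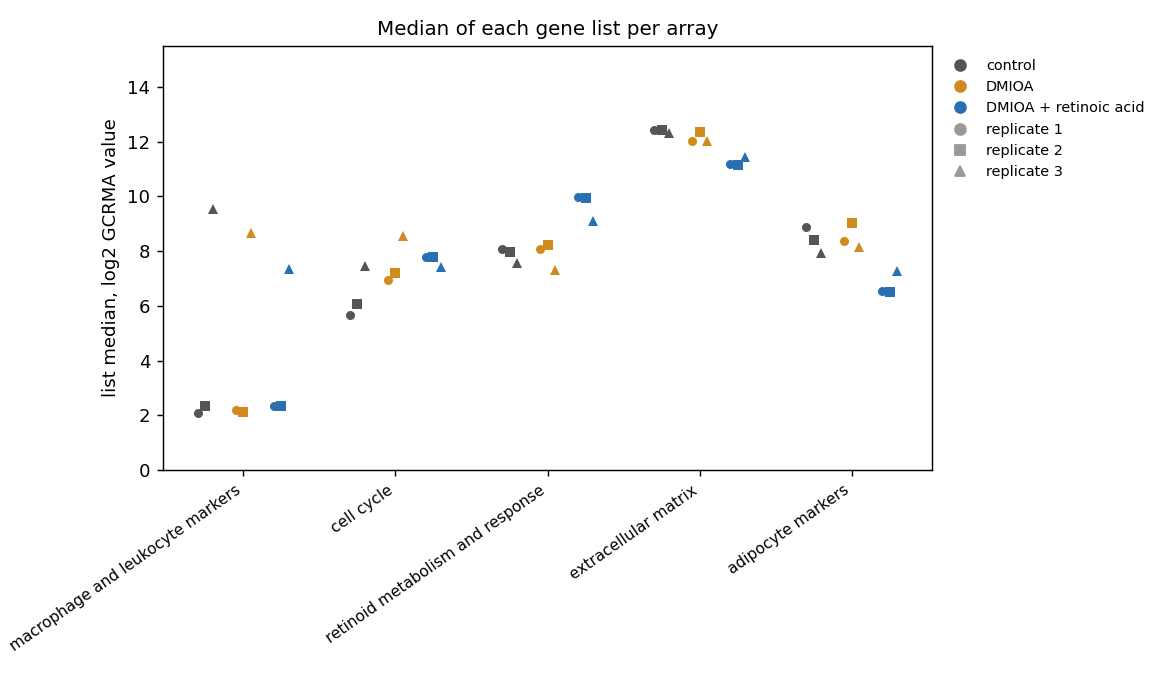
Median log2 GCRMA value of the measured members of 5 gene lists on each array (points; colours are groups, symbols replicate numbers). The macrophage and leukocyte median lies between 7.34 and 9.54 in replicate 3 and between 2.10 and 2.36 in replicates 1 and 2, while the retinoid list is highest in the retinoic acid array of each replicate number.

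The comparison of DMIOA with control asks what the adipogenic cocktail changed in these cells. DLL1 (gene ID 395820), which encodes a Notch ligand, had a mean of 7.31 ± 0.23 (SD, n = 3 arrays) in control and 4.08 ± 0.47 with DMIOA, at least 4.95-fold lower (limma, Benjamini-Hochberg adjusted p = 0.0129). POSTN (gene ID 395429), the matricellular protein periostin, fell from 13.39 ± 0.11 to 12.03 ± 0.08, a log2 change of -1.36 ± 0.11 (SE). MFAP5, a microfibril protein gene, changed by -1.91 ± 0.18, and the cytokine gene IL16 was at least 8.90-fold lower. CILP and KRT14 were at least 1.37-fold and 1.26-fold lower, and ADA, which encodes adenosine deaminase, changed by -1.10. Among the rises, ACADS, the short-chain acyl-CoA dehydrogenase of fatty acid oxidation, rose 2.09-fold (log2 1.06 ± 0.12, adjusted p = 0.0307), and MID1IP1, a regulator of acetyl-CoA carboxylase, rose 1.88-fold (adjusted p = 0.0399). Each of these genes moved in its direction in all 3 replicate numbers, which follows from groups that do not overlap and adds no support. The calls of POSTN, DLL1 and MFAP5 were lost without control replicate 1, control replicate 2 or DMIOA replicate 2 (adjusted p up to 0.0970, 0.0970 and 0.0994). Those of IL16, CILP, KRT14, ADA and ACADS were lost without these or without control replicate 3 or DMIOA replicate 3 (up to 0.199 over these arrays), and that of MID1IP1 without any 1 of the 6 arrays (up to 0.217).

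In total limma called 18 probe sets between DMIOA and control at an adjusted p under 0.05, 6 higher and 12 lower, and 1429 had an unadjusted p under 0.05. With the replicate number as a block, 159 were called, 61 higher and 98 lower, among them all 18. The naming rule for the largest rises and falls was also applied to the blocked fit, a use of it chosen after the data were seen. There it asked for the same direction in all 3 replicate numbers, in place of groups that do not overlap. Among the rises it added GCHFR and COL23A1, at least 3.78-fold and 6.21-fold higher. It also added the secreted factor gene C1QTNF3 (log2 1.73) and the cholesterol synthesis gene HSD17B7 (1.49, blocked adjusted p = 0.0484). Among the falls it added the sarcomere gene MYOM2, the proteoglycan gene BGN, PTPRQ and NCF4, at least 4.77-fold, 7.19-fold, 3.81-fold and 3.07-fold lower, and MYH1E, at least 4.86-fold lower. With the block and without DMIOA replicate 2, the only array left out of the blocked fit and an alternative added after the data were seen, 0 probe sets were called by limma (2013 at an unadjusted p under 0.05), so none of the 159 calls held without that array. Without the block the count was 0 without control replicate 1, without control replicate 2 or without DMIOA replicate 2 (983, 831 and 1092 probe sets at an unadjusted p under 0.05), 5 without DMIOA replicate 3 and 39 without DMIOA replicate 1. With replicates 1 and 2 of each group alone, an alternative added after the data were seen, it was 172.

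None of the 13 measured adipocyte markers was called between DMIOA and control, with or without the block; adjusted over the list alone, 2 rose, or 4 rose and 1 fell with the block. CIDEC, a lipid droplet protein gene, had 7.72 ± 1.83 with DMIOA and 3.81 ± 0.25 in control (adjusted p = 0.135, blocked 0.0732), with values of 6.20, 9.75 and 7.22 in DMIOA replicates 1, 2 and 3. The fatty acid carrier FABP4 had 12.17 ± 1.35 against 10.01 ± 0.41 (adjusted p = 0.652), and the lipid droplet gene PLIN2 11.85 ± 0.37 against 10.38 ± 0.56 (adjusted p = 0.221). PPARG, the receptor that drives fat-cell differentiation, had 8.91 ± 0.80 against 9.26 ± 1.86 (adjusted p = 0.950). LPL, which encodes lipoprotein lipase, had 5.75 ± 1.53 against 7.18 ± 0.86 (adjusted p = 0.581). The probe sets of CEBPA, PLIN1, ADIPOQ, SCD and DLK1 stayed below a log2 value of 5 on all arrays, with highest values of 2.61, 2.58, 2.99, 3.77 and 1.44. The list's median difference was 0.22, 0.66 and 1.49 in replicates 1, 2 and 3, the last in the arrays with high leukocyte markers. By camera the list had adjusted p = 0.0973, and 0.0245 without DMIOA replicate 1.

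As groups, 4 of 21 lists were called between DMIOA and control by camera with a preset correlation of 0.01, and these calls depend on that setting. The 36 cell cycle genes had a median log2 difference of 1.14 (Benjamini-Hochberg adjusted p = 1.21e-07, 0.601 with an estimated correlation), with 1.23, 0.83 and 1.16 in replicates 1, 2 and 3, and none was called on its own. CENPE, a mitotic kinesin gene, had the smallest p of that list, at 6.48 ± 0.73 against 5.09 ± 0.20 (limma adjusted p = 0.269). The 16 cholesterol synthesis genes moved up, with a median of 0.44 (adjusted p = 0.00144, 0.629 with an estimated correlation), though by replicate the medians were 0.82, 0.97 and -0.22. The 18 fatty acid oxidation and lipolysis genes moved up (median 0.33, adjusted p = 0.0266, blocked 0.120, 0.422 with an estimated correlation), 1 of them called, ACADS, and 4 adjusted over the list alone (6 higher and 2 lower with the block). The 22 contractile and TGF-beta response genes moved down (median -0.35, adjusted p = 0.000410, 0.422 with an estimated correlation). TGFB1 had 7.24 ± 0.36 against 8.62 ± 0.02 (adjusted p = 0.0626, blocked 0.0470). Without control replicate 1 or DMIOA replicate 2 the cholesterol list had adjusted p = 0.102 and 0.0613, and without control replicate 3 or DMIOA replicate 3 the fatty acid oxidation list had 0.236 and 0.0744. With an estimated correlation no list was called. The estimates for the cell cycle, cholesterol, fatty acid oxidation and contractile lists were 0.705, 0.788, 0.008 and 0.174, where the preset was 0.01. Fry called the fatty acid oxidation list (adjusted p = 0.0266). It did not call the cell cycle, cholesterol or contractile list (fry adjusted p = 0.387, 0.411 and 0.119). Of the 36 extracellular matrix genes POSTN was called, or 2 genes with the block, and the list's median was -0.02 (adjusted p = 0.126, and 0.0157 without DMIOA replicate 2).

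The comparison of DMIOA plus retinoic acid with DMIOA asks what retinoic acid changed in cells given the cocktail. The largest rise was that of CYP26A1 (gene ID 408183), the retinoic acid hydroxylase, which had 1.93 ± 0.10 with DMIOA and 11.97 ± 0.58 (SD, n = 3 arrays) with retinoic acid added, at least 125-fold higher (limma, Benjamini-Hochberg adjusted p = 1.73e-06). Its relative CYP26B1 was at least 10.1-fold higher (adjusted p = 1.10e-06), DHRS3, a retinaldehyde reductase gene, rose 12.3-fold (log2 3.62 ± 0.66), and the retinol-binding protein gene RBP5 rose 12.7-fold. Of the 14 measured retinoid metabolism and response genes 7 rose and 1 fell, or 8 and 2 with the block; adjusted over the list alone, 8 rose and 3 fell. The call of DHRS3 was lost without DMIOA replicate 2 or any 1 of the retinoic acid arrays (adjusted p up to 0.103). RARB, a retinoic acid receptor gene, had 10.90 ± 0.42 against 9.09 ± 1.18 (adjusted p = 0.264, blocked 0.0206).

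Among the genes with the largest rises with retinoic acid were TCF21 (gene ID 421697), a mesenchymal transcription factor gene, which was at least 84.1-fold higher (4.10 ± 0.77 to 11.39 ± 0.32, limma adjusted p = 7.91e-05), and FGF19, at least 11.1-fold higher. SERPINB1, SERPINB10B and the semaphorin receptor gene PLXNA4 were at least 20.3-fold, 11.8-fold and 3.91-fold higher, and the lipase gene LIPI rose as well. CYP24A1, which inactivates vitamin D, rose 29.3-fold to 13.66 ± 0.03. Of the 12 HOX genes, which set positional identity, 4 rose and 1 fell, or 6 and 2 with the block; adjusted over the list alone, 5 rose and 2 fell. HOXA4 rose by 4.01 ± 0.54 and HOXA6 by 1.94 ± 0.34 on the log2 scale, HOXA5 was at least 9.84-fold higher, and HOXD8 at least 3.04-fold lower. A second HOXA6 probe set had 1.25 and was not called. Without retinoic acid replicate 1 or 2 the calls of FGF19, HOXA5, HOXD8 and HOXA6 were lost (adjusted p up to 0.0835, 0.0924 and 0.137 for the first 3). They were also lost without DMIOA replicate 1 (FGF19, HOXA6), 2 (FGF19, HOXA5, HOXD8) or 3 (HOXA5, HOXA6, HOXD8). The HOX list as a whole had adjusted p = 0.161 by camera and 0.0391 with the block (0.541 with the block and an estimated correlation). Of the 12 HOX genes 8 were lower in replicate 3 than in replicates 1 and 2 (list camera adjusted p = 0.00408, 0.597 with an estimated correlation). That comparison was chosen after replicate 3 was seen to stand apart. The HOX medians with retinoic acid minus DMIOA were 0.52, 0.53 and 0.93 in replicates 1, 2 and 3.

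**Figure D3:**
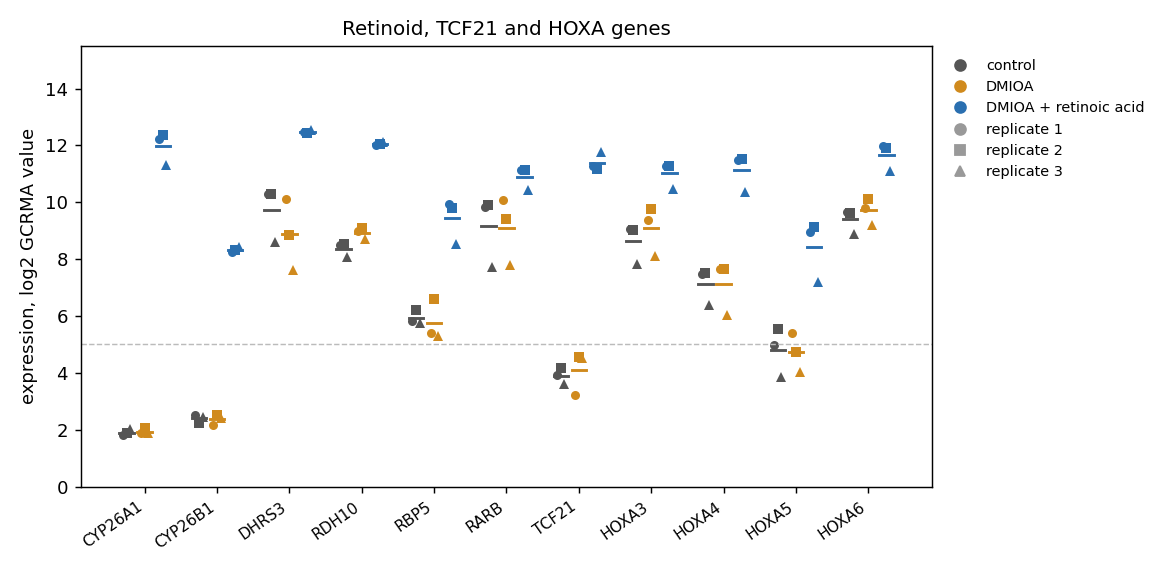
Log2 GCRMA values of retinoid genes, TCF21 and HOXA genes on the 9 arrays (points; bars are means of the 3 arrays of a group, colours groups, symbols replicate numbers; the dashed line is the log2 value of 5 used in the filter). CYP26A1 has a mean of 1.93 with DMIOA and 11.97 with retinoic acid added, and HOXA4 rose by 4.01 on the log2 scale.

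POSTN fell further with retinoic acid, from 12.03 ± 0.08 to 9.92 ± 0.07 (log2 change -2.11 ± 0.11, limma adjusted p = 7.91e-05), and the collagen genes COL6A2, COL6A3 and COL8A1 changed by -2.21 ± 0.27, -1.79 ± 0.16 and -1.75 ± 0.26. Of the 36 extracellular matrix genes 8 fell and 1 rose, or 11 and 2 with the block; adjusted over the list alone, 12 fell and 2 rose. The list moved down against other genes (median -0.30, camera adjusted p = 1.38e-06, 0.248 with an estimated correlation), by -0.39, -0.45 and -0.13 in replicates 1, 2 and 3. Of the 22 contractile and TGF-beta response genes ACTA2, the smooth muscle actin gene, fell (-1.71 ± 0.30) and TGFB3 rose (1.22 ± 0.21); with the block 3 fell and 1 rose. That list's camera adjusted p was 0.0126, or 0.401 with an estimated correlation, and its medians were -0.45, 0.07 and -0.48. It had adjusted p = 0.0943 without DMIOA replicate 1. The calls of COL8A1, ACTA2 and TGFB3 were lost without retinoic acid replicate 1 or 2 (adjusted p up to 0.0551, 0.101 and 0.0911), and that of ACTA2 without DMIOA replicate 3.

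The largest fitted log2 fall, a rank that rests on retinoic acid values below 5, was that of C1QTNF3 (gene ID 427430), a secreted adiponectin relative. It went from 11.51 ± 0.60 to 3.80 ± 0.74, at least 90.8-fold lower (limma adjusted p = 0.000104). The GTPase gene GEM, the water channel gene AQP1 and the sarcoglycan gene SGCD were at least 53.3-fold, 32.8-fold and 16.2-fold lower, METTL7A 25.2-fold and EMP1 15.4-fold. The caveolin gene CAV1 and the growth factor gene FGF7 were at least 4.97-fold and 5.89-fold lower. Of genes in the glucocorticoid list FKBP5 fell 7.69-fold and KLF15 8.28-fold, while ANGPTL4, an inhibitor of lipoprotein lipase, was at least 4.76-fold higher. The 15-gene glucocorticoid list had 1 rise and 2 falls, with a median of 0.16, a mean of -0.22 and a camera adjusted p of 0.944. Without retinoic acid replicate 1 or 2 the calls of AQP1, ANGPTL4, FKBP5 and KLF15 were lost (adjusted p up to 0.0539, 0.0576, 0.0990 and 0.0835). That of FKBP5 was also lost without DMIOA replicate 2 or 3, and that of KLF15 without DMIOA replicate 1 or 2 or retinoic acid replicate 3.

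Of the 13 adipocyte markers KLF15 was called lower with retinoic acid, and 4 were lower with the block; adjusted over the list alone, 1 rose and 1 fell, or 1 and 5 with the block. The list moved down (median -1.02, camera adjusted p = 0.00444, 0.248 with an estimated correlation), by -0.55, -1.28 and -0.76 in replicates 1, 2 and 3. FABP4 had 8.32 ± 3.44 against 12.17 ± 1.35 with DMIOA alone (limma adjusted p = 0.258). Its values with retinoic acid were 6.41 and 6.26 in replicates 1 and 2 and 12.28 in replicate 3, the array with high leukocyte markers, and without that array its adjusted p was 0.00780. PPARG had 7.76 ± 0.73 against 8.91 ± 0.80 (adjusted p = 0.608), PLIN2 11.22 ± 0.66 against 11.85 ± 0.37 (adjusted p = 0.501), and LPL 4.73 ± 1.10 against 5.75 ± 1.53 (adjusted p = 0.644, blocked 0.0447). Among cytokine genes IL6 rose 12.3-fold and the chemokine gene CCL4 fell 3.92-fold; another IL6 probe set had 0.42 and was not called. The interferon-inducible gene IFI27L2 rose 9.26-fold. Without retinoic acid replicate 1 or 2 or DMIOA replicate 3 the calls of IL6, CCL4 and IFI27L2 were lost (adjusted p up to 0.142, 0.123 and 0.165), as was that of IFI27L2 without DMIOA replicate 2 and that of CCL4 without DMIOA replicate 1 or retinoic acid replicate 3.

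**Figure D4:**
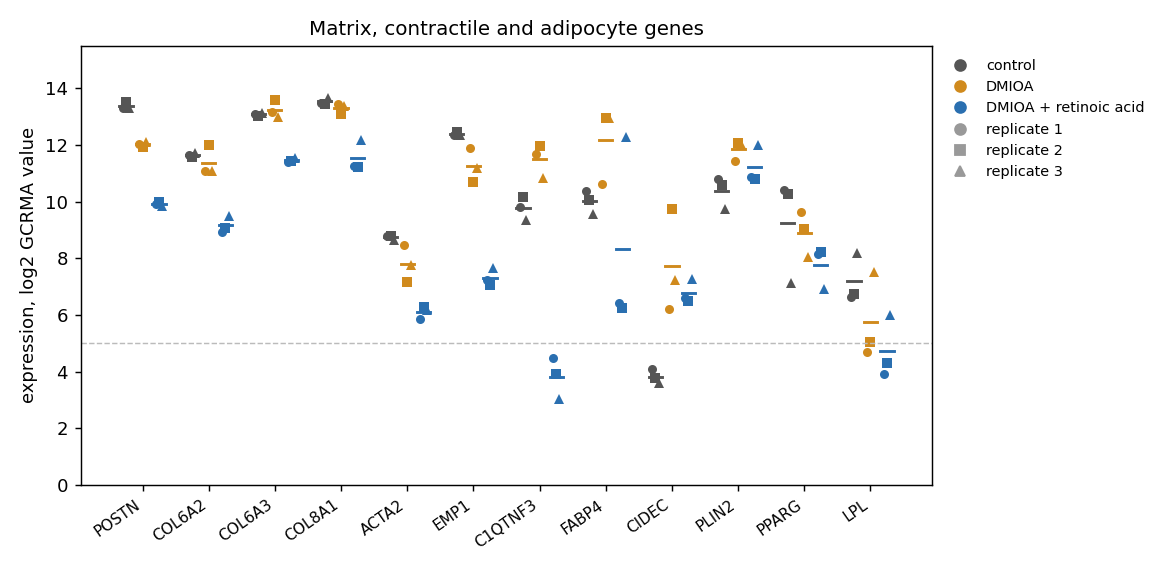
Log2 GCRMA values of matrix, contractile and adipocyte genes on the 9 arrays (points; bars are means of the 3 arrays of a group, colours groups, symbols replicate numbers; the dashed line is the log2 value of 5 used in the filter). POSTN goes from 13.39 in control to 12.03 with DMIOA and 9.92 with retinoic acid added, and FABP4 with retinoic acid lies at 6.41 and 6.26 in replicates 1 and 2 and at 12.28 in replicate 3.

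In total limma called 479 probe sets between DMIOA plus retinoic acid and DMIOA, 261 higher and 218 lower, of which 326 changed at least 2-fold. With the replicate block 1336 were called (686 higher, 650 lower), among them all 479. Of 21 lists camera called 8. Besides those above, the bone and cartilage, glucose transport and insulin, endothelial and skeletal muscle lists moved down, with adjusted p = 0.0483, 0.0483, 0.0489 and 0.0489 (blocked 0.0359, 0.0922, 0.0528 and 0.0322). None of the 8 was called with an estimated correlation; the retinoid list had 0.152 there and 9.72e-05 with the preset one, and these 4 had 0.248, 0.353, 0.401 and 0.248. The calls of these 4 were lost without DMIOA replicate 1 or retinoic acid replicate 1 or 2 (adjusted p up to 0.0984, 0.142, 0.188 and 0.150 over all arrays left out). They were also lost without DMIOA replicate 2 (glucose), DMIOA replicate 3 (endothelial, muscle) or retinoic acid replicate 3 (muscle). Without DMIOA replicate 1 or retinoic acid replicate 1 or 2 the count of probe sets was 313, 155 and 146, and the count of lists 3, 4 and 4. With replicates 1 and 2 alone the count of probe sets was 1517. The cell cycle list was not called (camera adjusted p = 0.695), with medians of 0.93, 0.90 and -1.10 in replicates 1, 2 and 3, but it had 0.000577 without DMIOA replicate 3.

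The comparison of DMIOA plus retinoic acid with control gives the joint change from untreated cells. CYP26A1 was at least 125-fold higher than in control (limma, Benjamini-Hochberg adjusted p = 1.69e-06), CYP26B1 at least 10.1-fold, and RDH10, a retinol dehydrogenase gene, 13.0-fold (8.36 ± 0.25 to 12.06 ± 0.06, SD, n = 3 arrays). TCF21 was at least 84.1-fold higher, and APOA1, the main protein of high-density lipoprotein, rose 26.8-fold to 14.15 ± 0.09. CCBE1, which encodes a secreted matrix protein that acts in lymphatic vessel growth, was at least 23.6-fold higher. HOXA3, HOXA4 and HOXA6 rose by 2.38 ± 0.51, 4.01 ± 0.54 and 2.26 ± 0.34 on the log2 scale, and HOXA5 was at least 9.56-fold higher; of the 12 HOX genes 5 rose and 1 fell (6 and 2 with the block), as against 5 and 2 adjusted over the list alone. The second HOXA6 probe set had 0.48 and was not called. Of the 14 retinoid genes 7 rose and 2 fell, as against 9 and 3 adjusted over the list alone (camera adjusted p = 0.00321, blocked 0.0603, 0.261 with an estimated correlation). The call of HOXA3 was lost without replicate 1 or 2 of control or of retinoic acid (adjusted p up to 0.0858), and that of CCBE1 without any 1 of the 6 arrays but control replicate 3 (up to 0.139).

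POSTN fell with DMIOA plus retinoic acid against control, from 13.39 ± 0.11 to 9.92 ± 0.07 (log2 change -3.47 ± 0.11, limma adjusted p = 5.30e-06), BGN fell (adjusted p = 0.0206), COL6A2 fell 5.57-fold, and FBN2, a fibrillin gene, was at least 4.18-fold lower. Of the 36 extracellular matrix genes 12 fell and 3 rose; adjusted over the list alone, 16 fell and 4 rose (camera adjusted p = 2.38e-06, 0.261 with an estimated correlation). ACTA2 fell 6.25-fold, the activin subunit gene INHBA 6.62-fold, TGFB1 3.01-fold and SMAD7 2.02-fold. Of the 22 contractile and TGF-beta response genes 6 fell (camera adjusted p = 6.46e-05, 0.261 with an estimated correlation), 9 adjusted over the list alone, where 1 rose. With the block 11 fell and 1 rose (12 and 2 adjusted over the list alone). The 7 bone and cartilage genes moved down (adjusted p = 0.0250, 0.261 with an estimated correlation), with COMP and DLX5 called; with the block 3 fell and 1 rose, or 5 and 1 adjusted over the list alone. EMP1 was 33.6-fold lower, and GEM and AQP1 at least 52.4-fold and 25.8-fold; DLL1, IL16, DOK7 and MYOM2 were at least 4.95-fold, 8.90-fold, 11.4-fold and 4.77-fold lower. The calls of BGN, INHBA, SMAD7 and COMP were lost without replicate 1 or 2 of control or of retinoic acid (adjusted p up to 0.0826, 0.0809, 0.0895 and 0.0747), and that of DLX5 without any 1 of the 6 arrays (up to 0.133).

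Of the 18 fatty acid oxidation and lipolysis genes 4 rose against control and 0 fell, with or without adjusting over the list alone (5 and 1 with the block, 5 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.168). HADHB rose by 0.82 ± 0.12 on the log2 scale, ACADS by 1.07 ± 0.12, ETFDH by 0.88 ± 0.16 and ANGPTL4, known to inhibit lipoprotein lipase, at least 6.08-fold (limma adjusted p = 0.00558, 0.00199, 0.0133 and 0.00264). ELOVL6, a fatty acid elongase gene, rose 2.02-fold, and MVK, which encodes mevalonate kinase, 3.06-fold. The cholesterol synthesis list moved up (median 0.60, adjusted p = 0.0281, blocked 0.0621, 0.614 with an estimated correlation), by 1.02, 0.90 and -0.13 in replicates 1, 2 and 3. Of its 16 genes 1 rose and 0 fell, or 3 and 0 with the block. Of the 13 adipocyte markers CIDEC was at least 3.46-fold higher (adjusted p = 0.0437), CEBPB rose 1.75-fold and KLF15 fell 6.12-fold; with the block 2 rose and 4 fell. PPARG had 7.76 ± 0.73 against 9.26 ± 1.86 (adjusted p = 0.298, blocked 0.0468), and LPL 4.73 ± 1.10 against 7.18 ± 0.86 (adjusted p = 0.0993, blocked 0.00181). FABP4 had 8.32 ± 3.44 against 10.01 ± 0.41 (adjusted p = 0.504), with differences of -3.98, -3.81 and 2.71 in replicates 1, 2 and 3, and it was called without retinoic acid replicate 3 (log2 -3.68, adjusted p = 0.0193). FKBP5 had 6.87 ± 0.32 against 8.40 ± 0.50 (adjusted p = 0.0863, blocked 0.0220). The 36 cell cycle genes moved up (median 1.47, camera adjusted p = 0.000169, 0.554 with an estimated correlation), by 2.32, 1.94 and 0.11; CENPE was called (limma adjusted p = 0.0498, blocked 0.0502), though another of its probe sets was not (log2 1.81), and 10 genes were with the block. Adjusted over the list alone, 0 were called by limma, or 23 higher and 1 lower with the block. Without replicate 1 or 2 of control or of retinoic acid the calls of ETFDH, MVK, CEBPB, KLF15, ELOVL6, CIDEC and CENPE were lost (adjusted p up to 0.0594, 0.0944, 0.0914, 0.0804, 0.0948, 0.131 and 0.166). That of ELOVL6 was also lost without retinoic acid replicate 3, that of CENPE without control replicate 3, and that of CIDEC without any 1 of the 6 arrays. The cholesterol list had adjusted p = 0.142, 0.0588 and 0.0698 without control replicate 1, control replicate 2 or retinoic acid replicate 3, and PPARG had 0.0238 without control replicate 3.

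In total limma called 1623 probe sets between DMIOA plus retinoic acid and control, 831 higher and 792 lower, of which 369 and 512 changed at least 2-fold. After cyclic loess between arrays the split was 612 higher and 935 lower. With the replicate block 3546 were called (1943 higher, 1603 lower), among them 1622 of the 1623. Of 21 lists camera called 7, or 4 with the block, and none with an estimated correlation; the endothelial list had adjusted p = 0.0478, blocked 0.0992 and 0.340 with an estimated correlation, and 0.231, 0.0609 and 0.0649 without control replicate 3 or retinoic acid replicate 1 or 2. Without control replicate 1 or 2 the count of probe sets was 665 and 573, and without retinoic acid replicate 1 or 2 it was 560 and 546. With replicates 1 and 2 alone it was 3620. The macrophage and leukocyte list was not called in any of the 3 comparisons (camera adjusted p = 0.294, 0.914 and 0.302), though it was between DMIOA and control without control replicate 1 (0.0486) or DMIOA replicate 3 (0.0121). These fits had no block. Without DMIOA replicate 3, of these 2 groups only control held a replicate 3 array, with a list median of 9.54. That call therefore cannot be read as an effect of DMIOA. Without control replicate 1, replicate 3 made up a larger part of the control group. The list's median difference in replicate 3 alone was -1.04 for DMIOA minus control and -2.17 for DMIOA plus retinoic acid minus control, from single arrays with no test.

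Whether retinoic acid turned back the DMIOA response was examined over probe sets called in both steps. That rule cannot show a reversal of genes not called in the first step, such as the adipocyte markers. Of the preset adipocyte, retinoid and glucocorticoid genes, none called there, FABP4, PLIN2, PDK4 and FKBP5 were higher with DMIOA in all 3 replicate numbers. Each was lower in all 3 when retinoic acid was added. DHRS3 went the other way, LPL was lower both times, and the rest were mixed in at least 1 step. Both steps share the DMIOA arrays, so these signs do not test a reversal. Without the block, 5 probe sets were called both for DMIOA against control and for retinoic acid plus DMIOA against DMIOA, 2 in opposite directions and 3 both times lower. ADA fell with DMIOA and rose when retinoic acid was added (log2 -1.10, then 2.55). So did a probe set of ANKRD1, which encodes a stress-responsive muscle protein and was named after its values were seen, by at least 2.15-fold and 1.79-fold; its brighter probe set was called in the second step alone. Both POSTN probe sets fell in both steps (-1.36, then -2.11, and -2.19, then -2.41). The last of the 5, DLL1, lay below a log2 value of 5 on all arrays of both groups in the second step, so no fall is given for it there. The count in opposite directions was 11 without DMIOA replicate 1 and 0 without any 1 of the other arrays. That in the same direction was 5 without control replicate 3 and 0 without control replicate 1 or 2, DMIOA replicate 2 or retinoic acid replicate 1 or 2. With the block 67 were shared, 29 in opposite directions and 38 in the same one (2 of the 38 below a log2 value of 5 in both groups of the second step), where independent lists would share 8.67 and 8.56. Both steps share the DMIOA arrays and the spread of each probe set, so the lists are not independent. That mark may be too low for either count. Genes with several probe sets, such as FAM20A and PXDN, also count more than once. Of the 29, 24 fell with DMIOA and rose when retinoic acid was added. None of the 67 held without DMIOA replicate 2, where the blocked fit called 0 probe sets between DMIOA and control. Across all 12329 probe sets, which are not independent replicates, the changes of both steps had r = 0.0786 and a covariance of 0.0233. Simulated unchanged arrays that share the DMIOA group gave r = -0.496 and a covariance of -0.0932, or -0.0298 with the spread of the blocked fit. The observed covariance lay 0.0531 above that with the blocked spread. It lay 0.116 above the first, but that spread holds replicate effects that the groups share and that cancel from both steps. The first simulation thus makes the covariance of unchanged arrays too negative. With 3 DMIOA arrays the shared group could not be split into parts of at least 2, so part of the 29 in opposite directions may come from the shared arrays.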

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

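The tests on replicates 1 and 2 alone, on the block without DMIOA replicate 2 and on the block with an estimated correlation were chosen after the result was seen. Of the values of named genes under all alternatives, 2775 stayed on their side of the threshold, 285 lost a call and 83 gained one. For lists these were 698, 94 and 27. For both, 0 changed direction with a call in the main or the alternative setting. A value called in neither setting counts as unchanged even where its sign changed. Centring the arrays or cyclic loess moved the median of all probe sets by under 0.1. The pseudocount alternative does not apply, because the values are on a log2 scale. With arrays, signal over background limits what can be seen, and dim probe sets were judged by level alone. The cause of the moves below was not tested, except where fewer arrays entered.

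With the replicate number as a block, the counts of probe sets called by limma were 159, 1336 and 3546 for DMIOA against control, retinoic acid plus DMIOA against DMIOA and against control, where 18, 479 and 1623 were called without it. The probe sets called in both steps went from 2 to 29 in opposite directions and from 3 to 38 in the same one, and 4 lists were called against control in place of 7. Other calls that the block changed stand beside the results, except for genes not described there. These were PECAM1 for DMIOA against control; CLDN1, ERG, GCLC, IRS4, MSX1, MYH1E and PDGFRB for retinoic acid plus DMIOA against DMIOA; and PTPRC and RARB against control, all called only with the block. With the block and without DMIOA replicate 2 the counts were 0 (2013 at an unadjusted p under 0.05), 1054 and 3898. With replicates 1 and 2 alone they were 172, 1517 and 3620, and the probe sets called in both steps were 27 and 66. With array weights they were 269, 1232 and 8317. With only the 6 arrays compared they were 0 (1137 at an unadjusted p under 0.05) and 216 for the first pair of comparisons, with fewer arrays to estimate the spread. An intensity trend with a robust prior gave 11 for DMIOA against control, and a 2-fold threshold gave 881 against control. Without the filter on dim probe sets, 1 probe set was called in opposite directions in both steps, and 4 lists between retinoic acid plus DMIOA and DMIOA in place of 8. With an estimated correlation, with or without the block, camera called 0, 0 and 0 lists, while fry called 1 for DMIOA against control and 11 for retinoic acid plus DMIOA against control. Leaving out 1 array at a time, the counts ran from 0 to 39, from 146 to 602 and from 546 to 1997. These fits had no block, so replicate 3 then had unequal shares of the groups. Calls of genes or lists gained or lost there may come from that. The probe sets called in both steps ran from 0 to 11 and from 0 to 5, and the lists from 3 to 6, from 3 to 7 and from 6 to 8. Of lists not described beside the results, without 1 array camera called the glucocorticoid list (adjusted p = 0.0245 without DMIOA replicate 1) and the preadipocyte list (0.0403 without DMIOA replicate 2) for DMIOA against control. It called the skeletal muscle list against control without control replicate 1 (0.0383) or retinoic acid replicate 1 or 2 (0.0475 and 0.0486).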

Other observations

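The comparison of replicate 3 with replicates 1 and 2 was chosen after replicate 3 was seen to stand apart. So were the tests of an array offset, of dilution and of a fixed FABP4 level in leukocytes. Between control and DMIOA plus retinoic acid MYH1E, a skeletal myosin heavy chain gene, fell from 8.04 ± 1.01 to 3.91 ± 0.44 (SD, n = 3 arrays, limma adjusted p = 0.00413), at least 8.24-fold, and PECAM1, an endothelial adhesion gene, at least 4.03-fold (adjusted p = 0.00705). Of the 18 glucose transport and insulin genes 4 fell and 0 rose, as against 6 and 2 adjusted over the list alone; with the block 6 fell and 4 rose (8 and 5 adjusted over the list alone). The 4 falls were those of IGFBP7 (-1.98 ± 0.24), IGFBP4 (-2.73 ± 0.52), IGF1R and LDHA. The list had a camera adjusted p of 0.0537, and 0.0469, 0.0475 and 0.0486 without control replicate 3 or retinoic acid replicate 1 or 2. The call of IGFBP4 was lost without replicate 1 or 2 of control or of retinoic acid (adjusted p up to 0.0643), and those of IGF1R and LDHA without any 1 of the 6 arrays but control replicate 3 (up to 0.112 and 0.117). Of the 13 interferon response genes IRF1 (at least 2.50-fold) and IFI27L2 (log2 3.33 ± 0.67) rose, the latter not without control replicate 2 or retinoic acid replicate 1 or 2 (adjusted p up to 0.0750); the list had 0.213, and 0.0265 without control replicate 3. Among 23 stress response genes HSPB1, a small heat shock protein gene, changed by -1.06 ± 0.16 (adjusted p = 0.00553). GPX1 fell and GCLC rose, calls lost without control replicate 1 or 2 (adjusted p up to 0.0679 and 0.0580) and, for GPX1, without retinoic acid replicate 1 or 2 (up to 0.0849). With the block 5 of the 23 fell and 2 rose.

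Replicate 3 differed from replicates 1 and 2 over the groups in 4385 of 12329 probe sets by limma, 1830 higher and 2555 lower. The comparison was picked because replicate 3 stood apart on these same arrays. Its counts and p-values therefore describe that difference and do not test it. The macrophage receptor gene CSF1R had 9.60, 9.42 and 8.95 in replicate 3 of control, DMIOA and retinoic acid, and at most 2.50 in replicates 1 and 2. The leukocyte antigen gene LY86 had 10.70, 9.75 and 8.20, and at most 1.94. Values below 5 were not told from background here, so no size is given for these 2 rises. CD36, which the adipocyte list also holds, had a fitted log2 difference of 7.80 ± 0.37. Of the 12 leukocyte genes 11 were higher, with a fitted list median of 5.81 (camera adjusted p = 7.47e-11, 0.597 with an estimated correlation). Only 4 of the 12 reached a log2 value of 5 in replicates 1 or 2, so the size of that median rests on values below this level. The cell cycle list was higher by a median of 0.65 (adjusted p = 0.000212, 0.912 with an estimated correlation), and the HOX list had -0.63 (0.00408, 0.597 with an estimated correlation). The endothelial list was also higher, by 1.37 (0.0432, 0.597 with an estimated correlation), as was the interferon list, by 0.56 (0.0194, 0.853 with an estimated correlation).

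For an array offset blind to cell type, the leukocyte list was set beside random lists. With no filter, 0 of 10000 random lists matched on replicates 1 and 2 reached the median of 3.25 over 22 list genes, and the highest had 0.294. The list was fixed before the data were examined, but it was picked for this test after it stood high on these arrays. The draws thus describe how far it stood out and are no independent test of an offset. The draws with no filter replaced earlier ones, after their outcomes were seen, on genes that passed the filter, which 8 of 12 list genes did through replicate 3 alone: lists matched on mean reached the list's 5.81 in 0 of 10000 draws (highest 3.01), and lists matched also on how genes passed in 11 (highest 6.35), from 72 genes that included those 8. RNA of macrophages or other leukocytes in those cultures is a candidate explanation, and a second leukocyte list of 45 genes, 8 of them measured, was higher by medians of 0.502, 0.857 and 0.843 in control, DMIOA and retinoic acid, between the bounds of 0.5 and 1 set before it was seen. This leaves the explanation open, because all 8 already reached a log2 value of 5 in replicates 1 or 2, where a high baseline can hide a small share; of 22 further genes below the filter, 6 reached that value in replicate 3 arrays and 0 in replicates 1 or 2. Other than that RNA, no biological explanation was tested, as the groups name none for replicate 3.

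Dilution of preadipocyte RNA by leukocyte RNA would lower matrix genes as much as the other falls in replicate 3. The extracellular matrix list had a median of 0.159 (SD over members 0.449) and was thus not lower, where the called falls had a median of -0.634. The called falls were picked for being lower, so their median is negative by selection. The list also holds bright genes on arrays that were normalized to each other, so the comparison does not decide on dilution.

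FABP4 in replicate 3 was 2.71 higher with DMIOA plus retinoic acid than in control, while in replicates 1 and 2 it differed by -3.98 and -3.81. The leukocyte list's median in replicate 3 differed by -2.20. Leukocytes with a fixed level of FABP4 relative to their markers would give a gap of at most about 0. It need not be near 0, as control replicates 1 and 2 had FABP4 at 10.39 and 10.07 with low leukocyte markers. The gap was 4.91, above the largest difference of 2.33 between replicates 1 and 2 of a group. The markers did not move alike: C1QC went from 10.43 to 6.33, while LAPTM5 stayed at 10.14, which would leave a gap near 2.71. On the list's median this argues against that source, on LAPTM5 only narrowly, and the difference rests on single arrays.

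Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. For DMIOA against control 2 of the 10 splits called at least as many probe sets, the real one with 18 and the highest other with 578. The latter set control replicates 1 and 2 and DMIOA replicate 1 against DMIOA replicate 2 and both replicate 3 arrays, and what its calls come from was not tested. Among the 4 splits that part all 3 pairs the highest other called 0, and with the block the real split called 159 and the highest other 0. For retinoic acid plus DMIOA against DMIOA the real split alone, 1 of 10, called 479, and the highest other 4. Against control it was also 1 of 10, with 1623 and a highest other of 0.

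Probe sets of other sequences, 689 in all, included 1 above the filter, with means of 13.49, 13.47 and 13.20 in control, DMIOA and DMIOA plus retinoic acid. By limma 0 of them were called in any comparison, with 27, 39 and 39 at an unadjusted p under 0.05.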
